A study of Mus musculus with 18 samples.

How the data were processed

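RNA of MC38 liver metastases was sequenced in 18 libraries, 10 in a table of LFD and HFD tumours and 8 in a table of shCon and shYap tumours. The deposited values are estimated counts per gene, which need not be whole. The tables' names point to the expectation-maximisation quantification of Partek, and STAR 2.7.3a, Partek and DESeq2 are named, with no role or order, per the submitters' processing notes, together with the builds GRCm38 and mm10. The annotation used for counting is not given in the sources used here. Library strand and read length are likewise not given, so reads of overlapping antisense genes cannot be separated.

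The LFD and HFD table held 22137 genes and the other 24778. The smallest mean of a gene over the libraries was 1 in the first table and 0 in the other, so the first had been filtered before deposit. Whole numbers made up 59.7% and 61.8% of the values of these tables, respectively. Symbol, start and strand matched GENCODE M21 for 97.4% and 97.2% of the genes. For 96.97% and 96.8% of them the deposited end was 1 above that of GENCODE, so ends are given here as in GENCODE. In the table of shCon and shYap, 23 symbols had been turned into dates, and 22 of them were restored from their positions. Total estimated counts per library were 17766207 to 18474191 in the first table and 17207214 to 21309950 in the other. Intervals and floors based on counts cover counting error only and leave out the variation between samples. PCR copies were not marked by molecular identifiers, so the counting error may be understated as well.

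Estimated counts were rounded to whole numbers. Each comparison was fitted in its own table with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, robust quasi-likelihood F test, no covariate), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. CPM values use the TMM-scaled library size, except the summed CPM of the sex-biased, Y-linked and hepatocyte lists, which use the unscaled library total. The standard error is the log2 fold change divided by the square root of F. A floor of 3 counts per library was used for folds against a group at 0, and intervals are at 95%. The 35 gene lists, the tests, the alternatives and the rule for named genes were chosen before the data were examined, and 34 lists with at least 5 genes were tested in each comparison. The adipocyte list had fewer and was not tested. Lists were tested with camera in limma 3.58.1 (preset correlation 0.01, log2 CPM with a prior count of 2), beside camera with an estimated correlation and fry. In both comparisons 0 of 34 lists passed in camera with an estimated correlation, against 19 and 20 with the preset one and 24 and 3 in fry. The smallest adjusted p was then 0.534 for HFD and 0.25 for shYap.

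The genes named are Yap1, Wwtr1, Ccn1, Ccn2 and Lats2; the 10 largest rises and 10 largest falls past the threshold with a mean of at least 5 CPM, without predicted genes, pseudogenes and receptor segments; up to 4 members of each list by p; and genes called in both comparisons. Where fewer than 5 genes passed, the 10 smallest p were named. Some genes under this rule are not reported here. Which of these genes are printed with values was decided after their values were seen. Albumin and Xist were singled out after their values were seen, as were the genes of the neutrophil granules and liver endothelium set apart in the closing observations. So were the lists of female-biased, male-biased and Y-linked genes, and the exact permutation tests of 38 library measures per comparison were added after the data were seen.

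Alternatives were DESeq2 1.42.0, limma voom, other scaling factors (RLE, upper quartile), no filter or 1 CPM as the filter, the replicate number as a block, the mean level of the hepatocyte list as a covariate, and each library left out in turn. Added after seeing the data were the sum of the closest HFD libraries, a fit without sex-biased genes, a block by the column numbers of the deposited table and a fit without the library of each of the shCon and shYap groups that lay farthest from its others. The libraries labelled shYap replicates 3 and 4 are numbered 4 and 5 in that table, and libraries are named here by the replicate number of their titles. Sex-biased lists were summed over the members found in both tables.

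The closest pairs of HFD libraries, replicates 1 and 2 and replicates 3 and 4, differed by a biological coefficient of variation of 7.3% and 6.4%, against 12.7% to 24.5% in the other HFD pairs. Their chi-square over degrees of freedom, 6.11 and 5.08, lay above sampling noise, which speaks against the same library deposited under both names but not against repeat preparations of 1 tumour. They were kept as the separate samples of the labels, and the fit was also run with each pair summed.

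The test was tried on simulated counts with known changes. For the LFD and HFD design, with 16234 genes, 43.3% of genes changed 2-fold and 90.9% of genes changed 4-fold were called, and 0.9% of the calls were unchanged genes. For the shCon and shYap design, with 16324 genes, 31.7% and 78.8% were called, and 6.8% of the calls were unchanged genes. With nothing changed, edgeR called 0 and 1 genes and DESeq2 3 and 7. Each gene was drawn independently and few were changed, whereas genes of the real libraries vary together. These shares and counts therefore need not hold for the real data.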

Results

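Liver metastases of MC38, a mouse colon carcinoma line, were grown in mice by injecting tumour cells into the spleen, and RNA of the tumour tissue was sequenced. There were 18 libraries in 4 groups: tumours of mice on a low-fat diet (LFD, n = 5), tumours of mice on a high-fat diet (HFD, n = 5), and tumours of high-fat-fed mice labelled with a control hairpin (shCon, n = 4) or with a hairpin against Yap (shYap, n = 4). The LFD and HFD libraries held 17766207 to 18474191 estimated counts each, and the shCon and shYap libraries 17207214 to 21309950. These groups stand in 2 separately quantified tables, so tests were run only within a table. No label says that the libraries of a group came from separate animals, so the p-values measure the spread between these samples.

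The first comparison asks how tumours of high-fat-fed mice differ from those of low-fat-fed mice. Genes of hepatocytes, of lymphocytes and of lipid synthesis were lower as lists in the HFD tumours, and 10 of 23 fibroblast and matrix genes and 8 of 16 genes of epithelial-mesenchymal transition were higher. These lists passed in camera with a preset correlation, and each had an adjusted p = 0.534 with an estimated correlation. The LFD libraries also held female RNA that the HFD libraries nearly lacked. Xist was at 101 ± 25.7 CPM in LFD and 0.186 ± 0.113 in HFD, and female-biased liver genes summed to 398 ± 106 and 1.48 ± 0.445 (SD, n = 5 each, unscaled library totals). The source of this RNA is not known and it is confounded with diet, so no difference between these groups can be credited to diet alone. Albumin, the main secretory product of hepatocytes, took 1.62% ± 1.21 of the counts in LFD and 0.0876% ± 0.0876 in HFD (SD, n = 5 each) and was lower in each HFD library than in any LFD library (two-sided exact permutation test, p = 0.00794, the smallest this design allows; adjusted over 38 library measures, 0.0177). Of 16340 genes tested, 6710 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 3178 higher and 3532 lower in HFD. Higher genes outnumbered lower ones with upper-quartile factors (3700 and 2999) and in limma voom (3284 and 3097), and 4233 passed with each of the 2 closest pairs of HFD libraries summed. Changes of over 1 on the log2 scale were falls in 2059 of the called genes and rises in 582. The groups did not overlap in 4997 genes, 30.6% of those tested, against 0.79% by chance.

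Hepatocyte genes fell together: 22 of 23 members were lower, with a median log2 fold change of -4.45. Among them were Apoa2 (-5.43 ± 0.76 SE), an apolipoprotein of high-density lipoprotein, Ttr (-5.36 ± 0.82), which carries thyroid hormone, and Cyp2e1 (-6.17 ± 0.92), a cytochrome of xenobiotic metabolism. The acute phase proteins, secreted by hepatocytes, fell in 8 of 11 members (median -2.97), with Hp at -2.99 ± 0.70 and Crp at -4.40 ± 0.89. Kupffer cells, the resident macrophages of the liver, had 6 of 9 markers lower (median -1.89), including Timd4 (-3.01 ± 0.58) and the iron exporter Slc40a1 (-2.34 ± 0.42). Adjusted over the list alone, 23 hepatocyte, 9 acute phase and 7 Kupffer cell genes were lower. The lists had adjusted p of 1.65e-10, 0.00068 and 0.00149 in camera with a preset correlation, and each had an adjusted p = 0.534 with an estimated correlation. With the mean hepatocyte level as a covariate the Kupffer cell list no longer passed (adjusted p = 0.0979) and the acute phase list turned higher (0.000316). This covariate correlates with the diet label at -0.88. Fits of HFD against LFD with it, here and below, therefore cannot separate liver share from diet.

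Lipid synthesis genes were also lower. Of the cholesterol synthesis list 18 of 20 genes fell (median -1.84, adjusted p = 2.48e-07), among them Insig1 (-3.29 ± 0.42), which holds back sterol synthesis, and Fdft1 (-2.13 ± 0.33), which makes squalene. Of the fatty acid synthesis list 14 of 15 fell and 1 rose (median -1.53, adjusted p = 5.76e-06). Fasn, the fatty acid synthase, fell by 1.80 on the log2 scale, from 488 ± 173 to 140 ± 4.03 CPM (SD, n = 5 each). Thrsp was at -8.39 ± 0.62, and Elovl6, which lengthens fatty acids, at -1.39 ± 0.18. The counts adjusted over the list alone were 20 lower for cholesterol synthesis, and 14 lower and 1 higher for fatty acid synthesis. Both lists had an adjusted p = 0.534 with an estimated correlation. Hepatocytes express many of these genes, and hepatocyte genes were lower in the same libraries, at a mean log2 CPM of 9.62 ± 1.45 in LFD and 5.04 ± 1.25 in HFD (SD, n = 5 each). With the hepatocyte covariate neither list passed (adjusted p = 0.89 and 0.159).

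The lists of fatty acid oxidation (10 of 20 lower, 1 higher, median -0.84) and lipid uptake and storage (9 of 14 lower, median -1.01) had adjusted p of 0.0135 and 0.0147. Dgat2, of triglyceride synthesis, was at -3.98 ± 0.82. All 11 mitochondrially encoded genes fell (median -0.68, adjusted p = 0.00109), such as mt-Nd2 at -1.25 ± 0.27, and so did 6 of 13 nuclear genes of oxidative phosphorylation (median -0.44, adjusted p = 0.0219). Of the stress response list 6 of 13 fell (median -0.29, adjusted p = 0.0135), with Xbp1 at -1.01 ± 0.25 and Herpud1 at -1.11 ± 0.26. Counts of lower genes adjusted over the list alone were 10, 9, 11, 7 and 8 in these 5 lists, in the order given, with 1 higher in the first. With an estimated correlation the adjusted p of these lists was 0.575, 0.569, 0.569, 0.598 and 0.534. Hepatocyte genes were lower in the same libraries. With the hepatocyte covariate the lists of fatty acid oxidation, lipid uptake and storage, and oxidative phosphorylation turned higher (adjusted p = 1.06e-05, 0.00644 and 0.0355), and mitochondrially encoded genes and the stress response did not pass (0.586 and 0.89). Without LFD replicate 5 the calls of lipid uptake and storage (0.0505) and oxidative phosphorylation (0.0939) were lost.

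Lymphocyte genes were lower in HFD. T cell genes fell in 15 of 16 members (median -1.85, adjusted p = 1.23e-05), such as Cd4 (-2.15 ± 0.29) and Zap70 (-2.10 ± 0.40), a kinase of T cell receptor signalling. Their mean log2 CPM was 2.495 ± 0.75 in LFD and 0.817 ± 0.567 in HFD (SD, n = 5 each), with 4 of 5 HFD libraries below every LFD library (two-sided exact permutation test, p = 0.0159; adjusted over 38 measures, 0.0288). Cytotoxic lymphocyte genes fell in 11 of 13 (median -1.53, adjusted p = 0.000397), with the granzyme Gzma at -2.34 ± 0.40 and the receptor Klrk1 at -2.04 ± 0.42. All 9 B cell genes were lower (median -2.47, adjusted p = 0.000252), among them Ighm (-2.28 ± 0.35). Dendritic cell genes fell in 10 of 11 (median -1.57, adjusted p = 0.00213) and neutrophil genes in 5 of 13 (median -0.78, adjusted p = 0.00207), with S100a8 at -3.16 ± 0.45. Of these lists 16 T cell, 12 cytotoxic, 9 B cell, 10 dendritic cell and 6 neutrophil genes were lower adjusted over the list alone. Each of these 5 lists had an adjusted p = 0.534 with an estimated correlation. Hepatocyte and Kupffer cell genes were lower in the same libraries, and with the hepatocyte covariate the T cell, cytotoxic, B cell, neutrophil and dendritic cell lists were lower at adjusted p of 1.3e-06, 6.11e-06, 2.12e-06, 0.00469 and 0.00673.

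Antigen presentation genes fell in 5 of 14 members (median -0.8, adjusted p = 0.0035), with H2-K1 at -0.81 ± 0.18 and B2m at -0.63 ± 0.16. All 5 red blood cell genes tested fell (median -3.79, adjusted p = 0.0346), such as Alas2 at -4.95 ± 0.79. In each 5 genes were lower adjusted over the list alone, and both lists had an adjusted p = 0.569 with an estimated correlation. The red blood cell call was lost without LFD replicate 5 (adjusted p = 0.0502). Antigen presentation stayed lower with the hepatocyte covariate (0.00138). The macrophage list had an adjusted p of 0.537, with 1 of 15 genes lower over all genes tested and 0 in edgeR adjusted over the list alone (2 at an unadjusted p under 0.05), and Adgre1, which encodes F4/80, was at -0.18 ± 0.13 (adjusted p = 0.293). Lists of alternative activation (3 of 11 lower) and classical activation (3 of 9 lower) had adjusted p of 0.0992 and 0.105, with 2 genes lower in each adjusted over the list alone. The alternative list passed without LFD replicate 3 (0.0375) or 5 (0.039), and the classical one without LFD replicate 2 (0.042), LFD replicate 5 (0.0466) or HFD replicate 4 (0.0431). Macrophage (0.000316) and classical activation genes (0.0458) passed as lower with the hepatocyte covariate. Arg1, an arginase found in hepatocytes and in alternatively activated macrophages, fell by 2.58 ± 0.53 on the log2 scale, but was at 0.48 with the hepatocyte covariate (adjusted p = 0.619 in edgeR).

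Matrix and mesenchymal genes were higher in HFD. Of the fibroblast and matrix list 10 of 23 rose (median 0.52, adjusted p = 0.00255), with Dcn at 1.11 ± 0.18, Tnc at 1.38 ± 0.28 and Col3a1 at 0.92 ± 0.19. Of the list of epithelial-mesenchymal transition 8 of 16 rose and 1 fell (median 0.44, adjusted p = 0.0131), including Twist2 (1.10 ± 0.15), Vim (1.01 ± 0.18) and Cd44 (0.64 ± 0.13). The numbers of higher genes adjusted over the list alone were 10 and 9, with 1 lower in the second list. Both lists had an adjusted p = 0.534 with an estimated correlation, and with the hepatocyte covariate their adjusted p was 0.0458 and 0.457. Spp1, which encodes osteopontin, rose by 1.93 ± 0.15, from 312 ± 76.6 to 1189 ± 86.3 CPM (SD, n = 5 each).

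Yap1, on chromosome 9 from 7931999 to 8004596 (GRCm38), was at 110 ± 9.36 CPM in LFD and 99.5 ± 3.66 in HFD (SD, n = 5 each). Its log2 fold change, from LFD to HFD, was -0.15 ± 0.07 SE (adjusted p = 0.122). Wwtr1, which encodes the Yap paralog TAZ, rose by 0.44 ± 0.07 (adjusted p = 0.00111). Of the Hippo pathway components 9 of 20 rose, among them Frmd6 (0.80 ± 0.09), Amot (0.94 ± 0.13) and Tead2 (0.83 ± 0.15), and the list had an adjusted p of 0.0519. Of 22 YAP/TAZ target genes 6 rose and 2 fell (adjusted p of the list 0.13). The risers included Myof (0.97 ± 0.18), Axl (0.67 ± 0.14) and Foxf2 (2.28 ± 0.24). Over all 16340 genes tested 3178 rose and 3532 fell, so the share of targets called in either direction was not above that of all genes. The common Yap readouts Ccn1 (-0.13 ± 0.22), Ccn2 (0.63 ± 0.57) and Lats2 (0.05 ± 0.07) did not pass the test (adjusted p = 0.668, 0.409 and 0.582). The same numbers passed adjusted over the list alone, 9 Hippo components higher, and 6 targets higher and 2 lower. The mean log2 CPM of each list was higher in each HFD library than in any LFD library, at 5.29 ± 0.0887 against 4.95 ± 0.13 for the targets and 6.247 ± 0.0413 against 5.995 ± 0.0961 for the Hippo components (SD, n = 5 each; two-sided exact permutation test, p = 0.00794 each; adjusted over 38 measures, 0.0177). Such separation was common in this comparison. The groups did not overlap in 30.6% of the genes tested, nor in the means of lists such as hepatocytes and epithelial-mesenchymal transition. In fry, which does not compare a list with other genes, the adjusted p was 0.0185 for the targets and 0.00942 for the components. In camera each had an adjusted p = 0.569 with an estimated correlation, and 0.833 and 0.586 with the hepatocyte covariate. The Hippo list passed in camera without LFD replicate 2 (0.044), 3 (0.034) or 4 (0.0429) or HFD replicate 1 (0.0401) or 5 (0.0349), and with the replicate number as a block (0.0468).

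The 10 largest rises among genes of at least 5 CPM were in Dmbt1, Nos1, Igf2bp2, Pi16, Hoxd3, Ly6c1, S100a4, Mmp28, H19 and F2rl1. S100a4, a calcium-binding protein of motile cells, went from 79.5 ± 85.2 to 606 ± 35.5 CPM, and Igf2bp2, an RNA-binding protein, from 5.94 ± 6.25 to 59.7 ± 6.29 CPM (SD, n = 5 each). Dmbt1 varied widely among the HFD libraries (32 ± 46.8 CPM).

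The 10 largest falls were in liver genes, mostly of drug and steroid metabolism, with Hamp2, a hepcidin, among them: Cyp3a41a, Cyp3a41b, Sult2a1, Cyp2b13, Hamp2, Cyp2a4, Cyp2c40, Sult2a2, Sult2a8 and Cyp1a2. Cyp3a41a had 0 counts in the HFD libraries and was at least 976-fold lower there, against a floor of 3 counts per library. Sult2a1 and Cyp2b13, also at 0, were at least 208-fold and at least 130-fold lower. Cyp2a4 had 2 counts over the 5 HFD libraries, a ratio of 3220 (95% counting interval 891 to 26600). These families hold near-identical members whose reads the authors' counting could split, so single members are uncertain. Several of these genes are known to be expressed mainly in female mouse liver, and Xist, the RNA of the inactive X chromosome, was found in every LFD library. Xist had 1406 to 2579 counts per LFD library and 1 to 6 per HFD library. The labels give no sex of the animals.

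Lists that did not pass in this comparison were immune checkpoints (5 of 10 lower and 2 higher, adjusted p = 0.105), cholangiocytes (2 of 6 higher and 1 lower, 0.191), epithelial and intestinal genes (1 of 8 lower, 0.676), hepatic stellate cells (2 of 9 higher and 1 lower, 0.651) and endothelial cells (3 of 15 lower and 1 higher, 0.216). Nor did hypoxia and glycolysis (6 of 19 higher and 1 lower, 0.105), cell cycle (1 of 26 higher, 0.24), interferon response (4 of 20 lower, 0.105), chemokines and colony-stimulating factors (3 of 15 lower and 1 higher, 0.696) and immediate early genes (1 of 11 higher, 0.408). Adjusted over the list alone, the numbers differed for interferon response (3 lower) and endothelial cells (3 lower, none higher), and none passed for epithelial and intestinal, cell cycle and immediate early genes. Interferon response passed without LFD replicate 2 (0.0154) or 5 (0.0392), hypoxia and glycolysis (0.0249) and immune checkpoints (0.0475) without LFD replicate 5, and cell cycle without LFD replicate 4 (0.0346). In the fit with the hepatocyte covariate, immune checkpoints (0.00778) and cell cycle (0.00949) passed as lower, and cholangiocytes (0.0023), epithelial and intestinal genes (0.0433), hepatic stellate cells (0.0018) and endothelial cells (0.0136) as higher, so that the cell cycle list went up without LFD replicate 4 and down with the covariate. The chemokine list had a median of 0.03, a mean of -0.42 and a test direction downwards. With the mean hepatocyte level as a covariate 1263 genes passed, of which 993 were among the 6710 and 868 had the same direction. The covariate and the diet label overlap, so this fit also removes diet differences that follow the hepatocyte level.

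**Figure D1:**
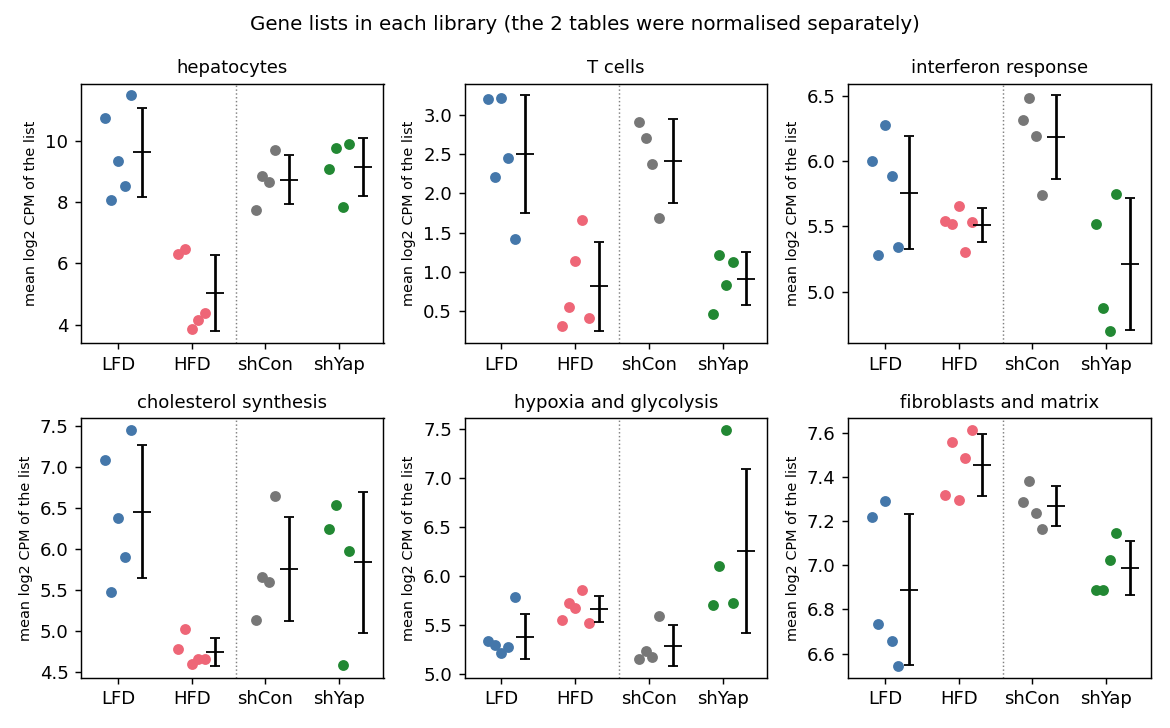
Mean log2 CPM of the genes of 6 lists in each library (points), with the mean and SD of each group (bars), for LFD and HFD (n = 5 each) and for shCon and shYap (n = 4 each), which come from separately normalised tables. Hepatocyte genes averaged 9.62 in LFD and 5.04 in HFD, and T cell genes 2.42 in shCon and 0.915 in shYap.

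The other comparison asks how tumours of high-fat-fed mice labelled with a hairpin against Yap differ from those with the control hairpin. Yap1 was at 78.1, 82.4, 73.8 and 77.4 CPM in shCon replicates 1 to 4 and at 71.6, 80.03, 81.4 and 70.5 CPM in the libraries labelled shYap replicates 1 to 4. The means were 77.9 ± 3.55 CPM in shCon and 75.9 ± 5.62 CPM in shYap (SD, n = 4 each), a log2 fold change of -0.04 ± 0.11 SE (adjusted p = 0.937). Its 95% interval of -0.28 to 0.2 allows a fall of at most 17.6% in this bulk tissue, so no knockdown of the target was seen and the group is written as the libraries labelled shYap. In the libraries labelled shYap, T cell, interferon response and antigen presentation genes were lower as lists in camera with a preset correlation and hypoxia and glycolysis genes were higher, most in shYap replicate 3. The lists had, in that order, adjusted p = 0.25, 0.273, 0.25 and 0.338 with an estimated correlation. No single gene of 16571 passed the threshold in edgeR: 0 were called, with 1804 at an unadjusted p under 0.05 (788 higher, 1016 lower). limma voom called 0 and DESeq2 410 (124 higher, 286 lower), and 23.3% of the genes that DESeq2 called in simulated data of this comparison were unchanged ones. That share depends on the number of genes simulated to change, so it is not the share among the 410. With nothing changed DESeq2 called 7 simulated genes. Leaving out shCon replicate 4 raised the number called in edgeR to 94 (17 higher, 77 lower), and leaving out shYap replicate 4 gave 1.

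**Figure D2:**
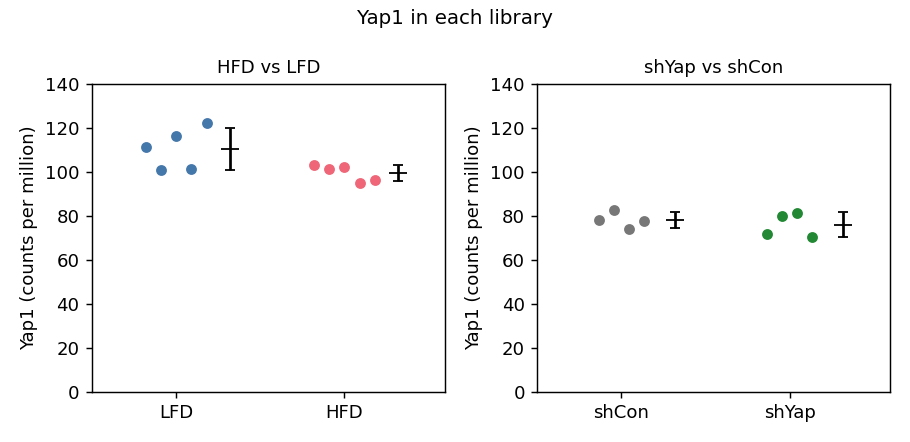
Yap1 CPM in each library (points), with the mean and SD of each group (bars), for LFD and HFD (left) and for shCon and shYap (right). The libraries labelled shYap average 75.9 CPM and the shCon libraries 77.9 CPM.

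T cell genes had a median log2 fold change of -1.68 (adjusted p of the list 4.61e-18), and 14 of 16 were lower adjusted over the list alone. No member of any list passed over all genes tested in edgeR. Cd3e was at -1.82 ± 0.37, Trac at -1.94 ± 0.35 and Cd2 at -2.12 ± 0.36. The mean T cell level was lower in each library labelled shYap than in any shCon library (exact permutation test, p = 0.0286, the smallest possible, adjusted over 38 measures 0.181). The means of dendritic cells, fibroblasts and matrix, hypoxia and glycolysis, antigen presentation and chemokines separated as fully, with the same p. The groups did not overlap in 6.6% of the genes tested, against 2.86% by chance. Cytotoxic lymphocyte genes (median -1.28, adjusted p = 2.38e-09) were lower in 8 of 12 members adjusted over the list alone, with Xcl1 at -2.43 ± 0.43 and Tbx21 at -2.12 ± 0.41. Dendritic cell genes (median -0.58, adjusted p = 7.99e-07) had 4 of 11 lower adjusted over the list alone, including Ccr7 (-1.46 ± 0.31). With an estimated correlation the adjusted p was 0.25 for T cells, 0.257 for cytotoxic lymphocytes and 0.25 for dendritic cells. Fibroblast and hypoxia genes moved in the same libraries, the former lower and the latter higher as lists.

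Interferon response genes had a median of -0.96 (adjusted p = 9.13e-16), with 19 of 20 lower adjusted over the list alone, such as Ifit2 (-0.87 ± 0.19) and Zbp1 (-1.28 ± 0.28). Antigen presentation genes had a median of -0.69 (adjusted p = 7.61e-11), with 11 of 14 lower adjusted over the list alone, among them the proteasome subunit Psmb9 (-0.86 ± 0.16) and Nlrc5 (-1.10 ± 0.23), an activator of MHC class I genes. With an estimated correlation the adjusted p was 0.273 and 0.25. The self-contained test fry passed 3 lists, which were T cells, dendritic cells and antigen presentation (adjusted p = 0.046 each).

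Hypoxia and glycolysis genes had a median of 1.04 (adjusted p = 9e-09; adjusted p = 0.338 with an estimated correlation), and 13 of 19 were higher adjusted over the list alone. The mean level was highest in shYap replicate 3, at a log2 CPM of 7.48, against 5.71 to 6.1 in the other libraries labelled shYap and 5.15 to 5.59 in shCon; without that replicate the list's adjusted p was 3.19e-05. That library also had the lowest mitochondrial share. Pgk1 and Eno1, glycolytic enzymes, were at 0.97 ± 0.23 and 0.65 ± 0.16, and Bnip3, a mitophagy receptor, at 1.97 ± 0.53. Stress response genes had a median of 0.53 (adjusted p = 3.66e-06; adjusted p = 0.273 with an estimated correlation), with 4 of 13 higher adjusted over the list alone, including Dnajb9 (0.75 ± 0.13). The cell cycle list had a median of -0.25 (adjusted p = 9.49e-05; adjusted p = 0.581 with an estimated correlation), with 3 of 26 lower adjusted over the list alone, and Bub1b was at -0.61 ± 0.11.

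Macrophage genes (median -0.31, adjusted p = 0.00445) and immune checkpoints (-0.46, 0.00445) were lower as lists, with 5 of 15 and 2 of 10 genes lower and 1 and 0 higher adjusted over the list alone. Cd68 was at -0.53 ± 0.16 and Fcgr1 at -0.62 ± 0.17. Fibroblast and matrix genes (median -0.2, adjusted p = 0.0332) had 5 of 23 lower and 1 higher adjusted over the list alone, with Thy1 at -1.36 ± 0.26. Chemokines (median -0.28, adjusted p = 0.019) had 3 of 15 lower adjusted over the list alone. With an estimated correlation the adjusted p was 0.338, 0.331, 0.273 and 0.257. The fibroblast call was lost without shYap replicate 2 (adjusted p = 0.12) and with the hepatocyte covariate (0.0816), and the chemokine call without shYap replicate 3 (0.112).

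Among the other lists that passed, B cells (median -0.31, adjusted p = 0.045) and mitochondrially encoded genes (-0.25, 0.0217) were lower. Neutrophils (0.58, 0.0163), hepatocytes (0.55, 0.0269), cholangiocytes (0.41, 0.0107), red blood cells (0.96, 0.045), fatty acid oxidation (0.33, 0.000419) and acute phase proteins (0.76, 0.00433) were higher. With an estimated correlation the adjusted p of these 8 lists was 0.581, 0.647, 0.581, 0.706, 0.273, 0.581, 0.331 and 0.581. Adjusted over the list alone, 1 B cell gene was lower and 1 neutrophil, 2 cholangiocyte and 1 fatty acid oxidation gene were higher, and no member of the other lists passed. Single libraries decided most of these calls. B cells did not pass without shCon replicate 4 (adjusted p = 0.318), shYap replicate 1 (0.352) or shYap replicate 3 (0.231), nor with a filter of 1 CPM (0.0941). Without shCon replicate 1 the calls of hepatocytes (0.476), acute phase proteins (0.0902), mitochondrially encoded genes (0.23), neutrophils (0.242) and red blood cells (0.268) were lost. Without shYap replicate 3 those of mitochondrially encoded genes (0.463), neutrophils (0.201) and red blood cells (0.342) were lost. Hepatocytes and red blood cells also lost their calls without shCon replicate 3 (0.0565 and 0.0821), shYap replicate 2 (0.297 and 0.0955) and shYap replicate 4 (0.475 and 0.174). With the hepatocyte covariate hepatocytes (0.717), cholangiocytes (0.106) and red blood cells (0.134) did not pass. Hepatocyte genes varied within both groups, with albumin at 1.14% ± 0.588 of the counts in shCon and 1.88% ± 1.12 in shYap (SD, n = 4 each; exact permutation test, p = 0.286).

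The 10 genes with the smallest p were lower in the libraries labelled shYap, each with an adjusted p of 0.149 in edgeR, and included Mmp25, Il21r, Fgl2, Bcl11b, Parvg, Ms4a4b, Notch1, Dock2 and Gm4070. Il21r, a cytokine receptor of lymphocytes, was at 22 ± 0.931 CPM in shCon and 8.57 ± 2.11 in shYap. Notch1 was at 59.6 ± 2.04 and 35.9 ± 3.59 CPM, and Dock2, a leukocyte migration factor, at 46.1 ± 4.68 and 27.5 ± 1.19 CPM (SD, n = 4 each).

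YAP/TAZ target genes had a median log2 fold change of 0.14 (adjusted p of the list 0.338) and Hippo components of 0.01 (0.777). Of the Hippo components 1 was higher adjusted over the list alone, and of the targets 0 in edgeR, where 1 was higher at an unadjusted p under 0.05. Ccn1 was at 0.73 ± 0.41, Ccn2 at 0.51 ± 0.36, Wwtr1 at 0.12 ± 0.22 and Lats2 at -0.002 ± 0.21 (adjusted p = 0.594, 0.676, 0.901 and 0.998). The other lists that did not pass were alternative (adjusted p = 0.816) and classical macrophage activation (0.0655), Kupffer cells (0.0621), epithelial and intestinal genes (0.216), hepatic stellate cells (0.187), endothelial cells (0.816), epithelial-mesenchymal transition (0.522), lipid uptake and storage (0.541), fatty acid synthesis (0.0746), cholesterol synthesis (0.732), oxidative phosphorylation (0.446) and immediate early genes (0.6). Adjusted over the list alone, 2 genes of alternative activation and 1 stellate cell gene were lower, 3 genes of classical activation were lower and 1 higher, and no other member of these lists passed. Without shCon replicate 4 or shYap replicate 3, Kupffer cells (0.00764 and 0.000295), fatty acid synthesis (0.000571 and 0.00221) and cholesterol synthesis (0.0445 and 0.00101) passed as higher. Fatty acid synthesis also passed without shYap replicate 4 (0.0477), and epithelial and intestinal genes passed as higher without shCon replicate 4 (0.0276) or shYap replicate 1 (0.0297). Classical activation passed as lower without shCon replicate 3 (0.0133), shCon replicate 4 (0.0464) or shYap replicate 1 (0.0282), and stellate cells as higher without shYap replicate 1 (0.0412). Cholesterol synthesis passed as lower with the hepatocyte covariate (0.0155), against higher in the fits above. The list of alternative activation had a median of 0.2, a mean of 0.01 and a test direction downwards.

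A further question is whether genes higher in the HFD tumours were lower in the libraries labelled shYap. Across 15946 genes tested in both, which are not independent replicates, the log2 fold changes correlated with Pearson's r = -0.029 and Spearman's rho = 0.012. No gene was called in both in edgeR, since 0 were called for shYap. With DESeq2 in both, 37 shared genes changed in opposite directions and 227 in the same direction. For independent lists 56.3 and 30 genes would be expected in the 2 opposite pairings and 24.1 and 69.8 in the pairings of like direction. Genes vary together and the overlap was not counted in regrouped libraries, so the distance from these numbers is no test. Among the shared genes 24 were higher in HFD and lower in shYap, 13 lower and then higher, 56 higher in both and 171 lower in both.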

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

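All tests of explanations in this part were chosen after the results were seen, except the refit of the exchanged shCon and shYap grouping with the hepatocyte covariate, which was read as undecided only after its result was seen because the covariate nearly follows that grouping. Of 172 sets of library values tested for an outlying library 6 stood out, and chance gives about 8.6. LFD replicate 1 was lowest in the Hippo component list (gap over range 0.784). LFD replicate 5 was highest for hypoxia and glycolysis (0.8) and immediate early genes (0.822). Among the shCon libraries, replicate 4 was highest for fatty acid oxidation (0.875) and fatty acid synthesis (0.885). Of the shYap libraries, replicate 3 had the lowest mitochondrial share, 5.343% against 7.253% to 7.538% (0.87).

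Hepatocyte genes were lower in the HFD tumours. The choice between these scaling factors is argued against, since the median of the hepatocyte list stayed at -4.34 with upper-quartile factors. Those factors moved the median of all genes only from -0.002 to 0.074, so they could not have changed the list much. More liver tissue around the LFD tumours may account for the pattern: the Kupffer cell list, a separate liver cell type, also had a median of -1.89. Any liver RNA added to the LFD samples could carry Kupffer cell transcripts. This test therefore cannot tell surrounding liver from the female liver RNA considered below. Whether diet also changed gene expression in hepatocytes was not tested, since the mean hepatocyte level and the diet label overlap.

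Female-biased liver genes and Xist were found in every LFD library, and the 12 female-biased genes found in both tables summed to 398 ± 106 CPM in LFD and 1.48 ± 0.445 in HFD (SD, n = 5 each). Summed CPM, here and below, use the unscaled library total. The shCon and shYap libraries held 0.0195 of the LFD level at a like hepatocyte level (43400 and 39000 CPM, in separately quantified tables), which argues against more of the same liver as the source. Female animals alone are argued against for the group as a whole, since male-biased genes relative to hepatocyte genes had a median 1.2 times that of shCon and shYap. In LFD replicates 2 and 4 male-biased genes were at 299 and 67.8 CPM, against 2570 to 7900 in the others. Y-linked genes were at 45.6 and 38.7 CPM there, against 25.2 to 35.6 in HFD and 34.7 to 48.9 in shCon and shYap. Both replicates therefore held RNA of male cells, whether of the animal or of the injected line, whose sex the labels do not give. Y-linked genes thus cannot tell the sex of these animals. Female animals for replicates 2 and 4, or a group of mixed sex, are not argued against. Replicate 4 had the highest female-biased sum of the LFD libraries (552 CPM) and replicate 2 the lowest (281 CPM). A like amount of female liver RNA in each LFD library is a candidate explanation: female-biased genes differed by 1.96 times between the highest and lowest library and hepatocyte genes by 6.15 times, but where such RNA came from stays open, and it is confounded with diet in these groups.

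T cell genes were lower in the libraries labelled shYap, and an effect of the hairpin stays open, untested, since no fall of Yap1 was seen. The list's call in camera with a preset correlation held, with a largest adjusted p of 3.38e-13 over the left-out libraries and 9.03e-13 with the hepatocyte covariate. Yet its unadjusted camera p was also 1.64e-16 and 3.9e-14 with shYap replicate 2 exchanged for shCon replicate 4 or 3. The call could thus hardly be lost in such fits, which do not decide whether liver share accounts for it. The mean T cell level was lower in each library labelled shYap than in any shCon library, so no single library made that difference. Of 35 splits of the 8 libraries 1, the split by the labels, had a smallest list p at a preset correlation as small as its own (1.35e-19, against 1.17e-17 in the next, for the hepatocyte list). That is the lowest share that 35 splits allow, in a test chosen after the T cell result was seen, so chance is not excluded. The mean T cell level had an exact permutation p of 0.181 adjusted over 38 measures, and the list an adjusted p = 0.25 with an estimated correlation. Exchanging shCon replicate 4 and shYap replicate 3, both numbered 4 in the deposited table, called 748 genes, moved the unadjusted p of the T cell list to 1.56e-05 and made the hepatocyte list's the smallest (1.28e-14), which points to a structure of the samples that may follow the hepatocyte level. With the covariate edgeR called 0 genes there, but the covariate correlates with that grouping at 0.86, and Yap1 was at -0.08 after the exchange (p = 0.484 in edgeR), so liver share and exchanged labels cannot be told apart.

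Of 100 splits of the LFD and HFD libraries (of 126) 1, the real split, gave as many genes, 6710 against at most 0 in the others in edgeR, where the real split had 8164 at an unadjusted p under 0.05, limma voom called 6381 and DESeq2 7289. Chance can be excluded for that count only if all these libraries are separate samples, which the closest HFD pairs leave open. No splits were run with those pairs summed. Chance cannot be excluded for the number of lists, since 17 splits gave 19 or more and the highest other gave 22. Nor can it be for the p of the HFD T cell list in camera with a preset correlation, 1.44e-06, since 23 of the 100 splits had one as small, with 1.44e-19 the smallest among the others; the exact permutation test of the mean T cell level gave p = 0.0159, or 0.0288 adjusted over 38 measures. For shYap edgeR called 0 genes (limma voom 0, DESeq2 410), a count that all 35 splits reach whatever the data, so it says nothing of chance; the highest other gave 748. Genes at an unadjusted p under 0.05 numbered 1804, reached in 4 of the 35 splits with 3686 in the highest other, so chance cannot be excluded for that count. Lists numbered 20 or more in 2 of the 35 splits, with 21 in the highest other, so it cannot be excluded there either. The correlation between the comparisons, -0.029, was matched or exceeded in size in 31 of 35 splits, the highest being 0.599.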

How the results depend on the processing

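The sum of the closest HFD libraries, the fit without sex-biased genes, the block by column numbers and the fit without the farthest shCon and shYap libraries were chosen after seeing the data. Against 6710, genes called for HFD numbered 2641 with a log2 fold change over 1 added and 1263 with the hepatocyte covariate. With the closest HFD libraries summed (fewer samples) they numbered 4233. Other tools, scalings and filters gave 6381 to 7323. The fit without sex-biased genes called 6681. It only drops the listed genes, so it cannot show what female liver RNA added to the other genes. Leaving out a library in turn gave 5523 to 7253. With a replicate block 4929 genes were called for HFD and 0 for shYap in edgeR, where 1804 had an unadjusted p under 0.05 without the block and DESeq2 called 410. The replicate numbers did not pair the samples: deviations of same-numbered libraries correlated from -0.5 to 0.31 (HFD) and from -0.05 to 0.18 (shYap), and not every sample correlated best with its own number. These are the numbers of the titles; shYap replicates 3 and 4 are numbered 4 and 5 in the deposited table, whose shared numbers 1, 2 and 4 gave correlations of 0.01, -0.05 and -0.39 and, as a replicate block, 0 genes in edgeR. With an estimated correlation 0 lists passed in camera in either comparison, against 19 (2 higher, 17 lower) and 20 (8 higher, 12 lower), and fry passed 24 (6 higher, 18 lower) and 3 (all lower). The 7 that fry added for HFD were YAP/TAZ targets, Hippo components, alternative and classical activation, immune checkpoints, cholangiocytes, and hypoxia and glycolysis (adjusted p of 0.00942 to 0.0449), and fatty acid oxidation (0.0873) and oxidative phosphorylation (0.101) did not pass in it. Lists with the hepatocyte covariate numbered 20 (9 higher, 11 lower) and 17 (5 higher, 12 lower), and without the farthest shCon and shYap libraries 19 (10 higher, 9 lower). The replicate block gave 20 and 22 lists, adding Hippo components for HFD (0.0468) and classical activation (0.0377) and Kupffer cells (0.0099) for shYap; by column numbers it gave 17 for shYap, without hepatocytes (0.6), cholangiocytes (0.0573) and acute phase proteins (0.0893). For shYap edgeR called 0 genes, DESeq2 410, the hepatocyte covariate 1, and leaving out a library gave 0 to 94 (94 without shCon replicate 4, 1 without shYap replicate 4). Without shCon replicate 4 and shYap replicate 3 together 1255 were called; these were left out for lying farthest from their groups, which narrows the spread by construction, so this is no estimate of the effect. Genes called in both comparisons in opposite directions were 37 with DESeq2 in both and 35 at an unadjusted p under 0.01 in both, against 0 in edgeR. Those called in the same direction were 227, 204 and 0, in that order. The correlation between the comparisons lay between -0.208 and 0.124 over the left-out libraries and was 0.195 with the covariate. Yap1 kept its side of the threshold in every fit run, from -0.18 to 0.09 for HFD and -0.08 to 0.01 for shYap. With the hepatocyte covariate 9 named genes that fell in HFD had positive log2 values, past no threshold: Arg1 0.48, Timd4 0.18, Clec4g 0.2, Dgat2 0.41, Hp 0.59, Crp 0.28, mt-Nd2 0.05, Xbp1 0.25 and Herpud1 0.09. The covariate correlates with the diet label at -0.88, and the cause of the other changes was not tested. At this depth and number of libraries 31.7% of genes simulated, independently of each other, to change 2-fold in the shYap design were called. Smaller changes could therefore not be seen reliably.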

Other observations

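No tests of explanations stand in this part, and its genes were set apart after their values were seen. Y-linked genes were read in every library, at 58.9 ± 21.1 summed CPM in LFD and 29.4 ± 4.84 in HFD (SD, n = 5 each), and Xist was at 0 to 4 counts in the shCon and shYap libraries. The liver endothelial genes Clec4g (-3.99 ± 0.77) and Stab2 (-2.37 ± 0.52) fell in the HFD tumours with the hepatocyte genes, in edgeR with adjusted p of 0.00323 and 0.00612. The neutrophil granule genes Camp and Ngp fell too, Ngp by 7.04 ± 0.52, and Camp had 1 count over the HFD libraries, a ratio of 321 (95% counting interval 57.7 to 12700). Angptl4 rose by 1.51 ± 0.30 and Aldoa by 0.71 ± 0.12, although their list did not pass.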
